A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

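Nucleosome positions were mapped in the budding yeast Saccharomyces cerevisiae by sequencing mononucleosomal DNA. Per the labels' protocols, the strain carried MYC-tagged Pho4 and HA-tagged Cbf1. Pho4 is the transcription factor that activates phosphate-starvation genes, and Cbf1 is a second factor that binds the same CACGTG core sequence. Log-phase cells were kept without phosphate for 3 hours and then moved for 80 minutes to medium with 0 mM phosphate (starvation) or 10 mM phosphate (high phosphate). Chromatin was digested with micrococcal nuclease, an enzyme that cuts linker DNA between nucleosomes, crosslinks were reversed, and mononucleosome-sized DNA was purified from a gel and sequenced on an Illumina Genome Analyzer without an antibody. A short label on each sample mentions sonication, which the protocols do not describe. Each condition had 1 library, so no test between conditions was possible and no p-value between them is given.

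Per the labels' protocols, tags were placed on the October 2003 yeast genome release (sacCer1). The aligner, its settings and the read length are not given in the sources used here. Each deposited file lists a chromosome, a position and a strand for every tag with a unique placement, with no header and no level attached. In both files every combination of position and strand occurs once (0 repeated rows), so repeat tags at the same position and strand had been collapsed before deposit. This caps the count at 1 tag per position and strand and compresses strong positions more in the deeper library. Nuclear tags filled 4.16% of position-strand combinations up to the last tagged position of each chromosome in the starvation library and 10.8% in the high phosphate library. At 275 stretches of more than 400 bp without tags, the first and the last minus-strand position most often lay 19 bp to the right of the plus-strand one. Minus-strand positions were therefore taken as the 5′ ends of reads, as plus-strand positions are. Whether positions count from 0 or 1 is not stated; they were used as deposited.

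Groups came from the sample titles. Tags were moved 73 bp towards the middle of the fragment and counted in 1 kb bins of the 16 nuclear chromosomes. Counts were scaled to the nuclear tag total of each library. The log2 ratio of starvation over high phosphate was given a 95% exact conditional binomial (Clopper-Pearson) interval for bins with at least 20 tags over both libraries. SDs over bins used a pseudocount of 0.5 and were set beside binomial draws with the same bin totals, which carry counting error alone. Fragment length was the lag (80 to 250 bp) with most pairs of a plus-strand and a minus-strand tag, after an 11 bp running mean. The nucleosome repeat was the slope over the first 5 peaks of the distances between moved tags, the first being sought at 120 to 220 bp. Peak heights were divided by the mean number of pairs at 2000 to 3000 bp. Their spread is the SD over the 16 chromosomes of the same library, which are not biological replicates. Chromosome shares are of all tags, mitochondrial included, and carry 95% exact binomial (Clopper-Pearson) intervals. All intervals cover counting error only, and tags are not independent molecules, so the spread between cultures is unknown.

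For nucleosome maps, 2 disjoint subsets of 500000 nuclear tags were drawn from each library, so that tag totals were equal. Dyads, the midpoints of nucleosomes, were local maxima of the moved-tag density smoothed with a Gaussian SD of 20 bp, at least 120 bp apart and above the genome mean. Dyads within 20 bp were called matched. Chance matching was measured by moving one map by 20 random distances. Gaps were stretches of 230 to 400 bp between neighbouring dyads, and their filling was measured in tags that had not been used to call them. The nucleosome maps, the 20 kb windows, the runs of bins, the distance from chromosome ends, the relation to chromosome length, the mitochondrial bins and the peak heights were chosen after the data had been seen. The other measures and the naming rule were fixed before the data were examined.

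The 1 kb bins named in the text are the 10 largest falls and the 10 largest rises, ranked by the interval bound nearest to 0. This was the rule set for the case in which no annotation of the files' build could be used. Comparisons planned at promoters, at gene starts, at CACGTG sites and for 12 gene lists were not analysed here. The gene table at hand is for assembly R64, the tags carry no sequence, and coordinates of different builds were not mixed. No gene is therefore named as a result. The alternatives tried were scaling to the median 10 kb bin, 1 tag per position and strand, unmoved tags, other bin sizes and thinning of the deeper library to 1001229 tags. A correction for filled positions was added, which replaces the count of tags in each 10 bp window and strand by the Poisson mean that would leave the observed share of positions empty. Simulated data were used to test the procedure. Among 11563 simulated bins, 95.4% of the intervals held the true ratio, and the median of 50 bins simulated 4-fold lower was −2.06 on the log2 scale. In 3 simulated arrays the fragment length was recovered within 3 bp and the repeat within 0.4 bp. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.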

Results

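The data comprise 2 genome-wide maps of mononucleosomal DNA from S. cerevisiae, 1 from cells held in 0 mM phosphate and 1 from cells returned to 10 mM phosphate for 80 minutes. The starvation library held 1012969 uniquely placed tags and the high phosphate library 2603132. Of these, 1001229 and 2598022 lay on the 16 nuclear chromosomes, which is 83.2 and 216 tags per kb. The median 1 kb bin held 74 tags in the starvation library and 225 in the high phosphate library. Tags were split evenly between the strands, with 50.1% on the plus strand in both libraries. With 1 library per condition, none of the differences below has a replicate check. A difference between these libraries cannot be told apart from a difference between the conditions.

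Regular nucleosome arrays were present under both conditions, and their spacing was nearly equal. The nucleosome repeat, the distance from one nucleosome to the next along the DNA, was 163.6 bp in starvation and 163.3 bp in high phosphate. The mean difference over chromosomes, starvation minus high phosphate, was 0.044 bp with an SD of 2.17 bp (n = 16 chromosomes). The first array peak lay at 169 bp in starvation and 170 bp in high phosphate. The slope used 5 array peaks in each library, a number set in advance, and the last of them lay at 824 bp in both.

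The sequenced fragments were longer in the starvation library. The offset between the strands, which measures fragment length, was 155 bp in starvation and 142 bp in high phosphate. The difference was 13 ± 1.83 bp (SD, n = 16 chromosomes) and had the same sign on 16 of 16 chromosomes. On the mitochondrial genome, which carries no nucleosomes, the offset was also longer in starvation, 134 against 125 bp. The difference was thus not limited to nucleosomal DNA. The peaks of the tag-pair distances also stood higher in starvation. At the fragment length, plus-minus pairs were 2.79 times as frequent as at distant positions in starvation, with an SD over chromosomes of 0.081. In high phosphate they were 1.38 times as frequent, with an SD of 0.044. The first array peak stood at 1.56 times the distant level (SD 0.071) in starvation and at 1.24 times (SD 0.029) in high phosphate. Both heights were greater in starvation on 16 of 16 chromosomes. The trough below the fragment length was not deeper, at 0.770 times the distant level in starvation and 0.744 in high phosphate. Its mean difference over chromosomes was 0.015 with an SD of 0.041.

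**Figure D1:**
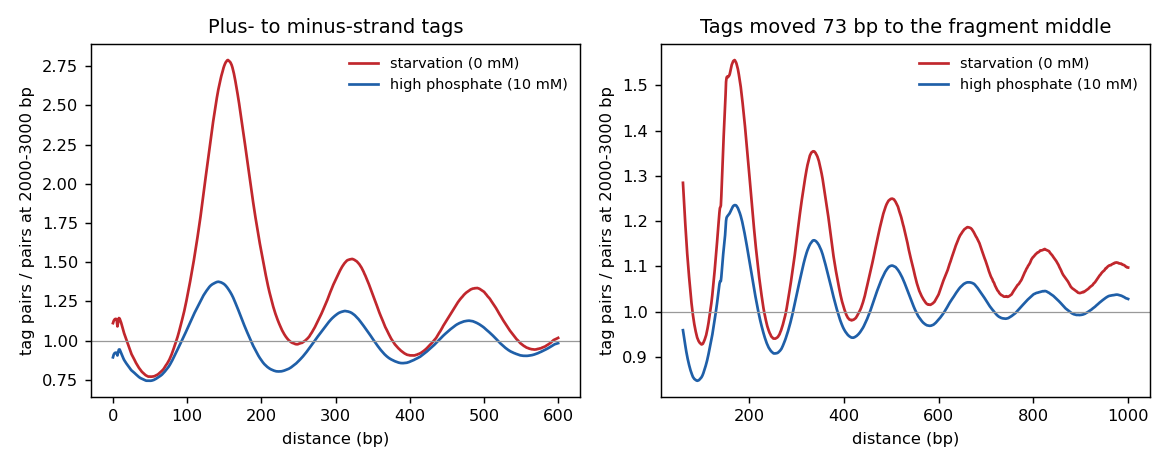
Pairs of tags by distance in bp, relative to pairs at 2000 to 3000 bp, for plus-to-minus-strand tags (left) and for tags moved 73 bp to the fragment middle (right). Lines are the 2 libraries; the starvation fragment peak lies at 155 bp and reaches 2.79, the high phosphate peak lies at 142 bp and reaches 1.38, and the array peaks fall at nearly the same distances.

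Nucleosome positions matched across the libraries more often than displaced maps did. Of dyads called in subsets of the starvation library, 53.5% lay within 20 bp of a dyad of the high phosphate library (range 53.2% to 53.8% over 4 pairs of subsets). Randomly displaced maps matched at 18.6%. Between 2 disjoint subsets of the starvation library the share was 57.2%, with 15.2% for displaced maps. With matching within 40 bp this order turned, to 70.7% across libraries and 70.2% within starvation. Displaced maps then matched at 36.5% and 29.7%, so the order does not turn relative to that level. Of the dyads called in high phosphate, 43.5% (43.2% to 43.7%) lay within 20 bp of a starvation dyad, with 15.1% for displaced maps. Between 2 subsets of the high phosphate library the share was 47.2%, with 18.5% for displaced maps. Subsets of the same library share no position and strand because repeat tags were collapsed, while subsets of different libraries can. The shares within and across libraries are therefore not fully alike. At this depth many dyads are not placed repeatably even within a library.

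With equal tag totals the starvation subsets gave fewer dyads than the high phosphate subsets, 41748 and 41832 against 51479 and 51441. Dyads had to stand above the genome mean, so stretches of low density in a library contributed few, and the equal totals do not undo the stronger collapsing of the deeper library. The median distance between neighbouring dyads was 207 and 206 bp in the starvation subsets and 188 bp in both high phosphate subsets. A dyad that is not called lengthens this distance, which the repeat from tag pairs does not depend on. Relative to the flanking dyads, wide gaps between nucleosomes held somewhat fewer tags in starvation. At 13301 gaps of 230 to 400 bp called in high phosphate, the middle of the gap held 42.2% of the tags at the flanking dyads in starvation (SD over chromosomes 2.44 percentage points) and 48.2% in high phosphate (SD 1.91). The gap middles held similar numbers of tags, 26169 in starvation and 27145 in high phosphate, while the flanks held 62078 and 56297. These counts were not corrected for filled positions. Stronger collapsing at the flanks in the deeper library would act in the same direction, so its part in the contrast is not known. At 11981 gaps called in starvation the values were 25.7% (SD 1.13) and 52.1% (SD 1.59), a contrast that the calling in that library itself enlarges. For both sets of gaps, the filling relative to the flanks was higher in high phosphate on 16 of 16 chromosomes.

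Tags were distributed differently over the chromosomes in the 2 libraries. The 6 shortest nuclear chromosomes each took a larger share in starvation. Chromosome 1 held 1.94% of tags in starvation (95% exact binomial interval 1.92% to 1.97%) and 1.70% in high phosphate (1.68% to 1.71%), which is 14.4% more. Chromosome 3 held 2.93% in starvation and 2.64% in high phosphate, and chromosome 6 held 2.41% and 2.27%. Chromosomes 5, 8 and 9 had log2 ratios of 0.076, 0.070 and 0.094. Among the 10 longer chromosomes, chromosome 14 was higher in starvation, with a log2 ratio of 0.055. Chromosome 10, with a log2 ratio of −0.0070, had an interval that included 0, and the other 8 were lower. These shares are of all tags, mitochondrial included. Scaled to nuclear tags, every ratio rose by 0.014, chromosome 10 turned to 0.0069 and chromosome 12 moved from −0.016 to −0.0021 with an interval that included 0, which left 7 lower. Chromosome 4, the longest, held 11.5% in starvation and 12.3% in high phosphate. These intervals cover counting error only.

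**Figure D2:**
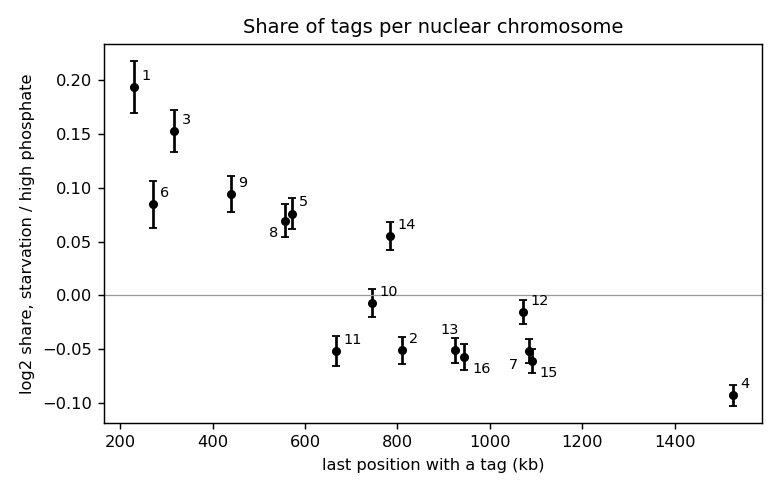
Log2 ratio of the share of all tags, starvation over high phosphate, for each of the 16 nuclear chromosomes against its last position with a tag in kb; bars are 95% exact intervals for counting error. Chromosome 1 lies highest at 0.19 and chromosome 4 lowest at −0.093.

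The mitochondrial genome took 5.90 times as large a share of tags in starvation (95% exact interval 5.71 to 6.10). It held 11740 tags, or 1.16% (1.14% to 1.18%), in starvation and 5110 tags, or 0.196% (0.191% to 0.202%), in high phosphate.

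Local tag density differed widely between the libraries. Over 11560 bins of 1 kb, the log2 ratio of starvation over high phosphate had an SD of 0.68. Counting error alone gave 0.19, and the excess over it was 0.66. In 1020 bins (8.82%) starvation was at least 2-fold lower and in 747 bins (6.46%) at least 2-fold higher, where counting error alone gave 1 and 2 bins. The balance of these directions depends on the scaling and on the bin size. With the median 10 kb bin set to 0, every log2 ratio rose by 0.062, and the counts became 784 lower and 880 higher. The share of higher bins among them moved from 42.3% to 52.9%. In 200 bp bins 13319 were lower and 7380 higher, where counting error alone gave 1085 and 540. In 5 kb bins 10 were lower and 36 higher, where it gave 2 and 0. The excess SD was 0.92 in 200 bp bins, 0.43 in 5 kb bins, 0.33 in 10 kb bins and 0.17 in 50 kb bins.

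**Figure D3:**
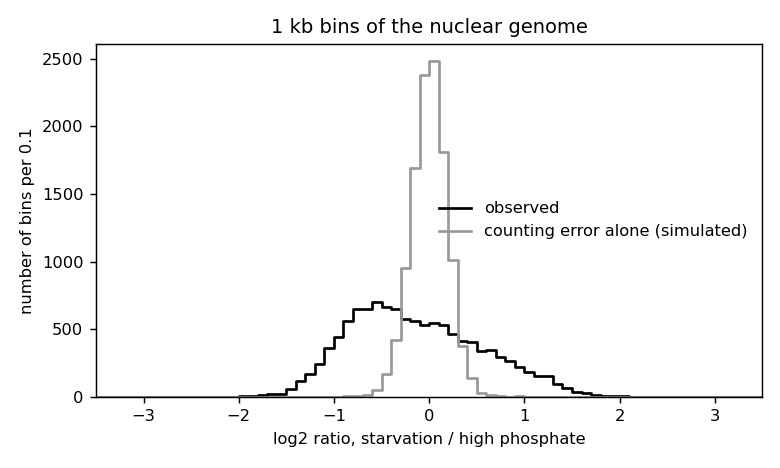
Number of 1 kb bins per 0.1 step of the log2 ratio, starvation over high phosphate, as observed (black) and with counting error alone (grey, simulated). The observed SD is 0.68 and the simulated SD 0.19.

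The 10 named bins with lower density in starvation were 3.38 to 4.92 times lower, and they stood further from the median bin in starvation than in high phosphate. They held 13 to 30 starvation tags, or 0.18 to 0.41 of the median bin of that library. In high phosphate they held 158 to 263 tags, or 0.70 to 1.17 of the median bin. The first by the ranking rule lay on chromosome 5 from 433001 to 434000 (build of the files, sacCer1). It had 13 tags in starvation and 166 in high phosphate, a log2 ratio of −2.30 (95% exact interval −3.24 to −1.49). Next came chromosome 4 from 379001 to 380000, with 14 and 164 tags and a log2 ratio of −2.17 (−3.08 to −1.39). Chromosome 13 from 613001 to 614000 followed, with 22 and 231 tags and a log2 ratio of −2.02 (−2.72 to −1.38). The remaining lower bins began at 1138001 on chromosome 4, 243001 on chromosome 5, 546001 on chromosome 11, 604001 on chromosome 13, and 152001, 645001 and 1020001 on chromosome 15. Among the 20 bins adjoining them, 15 were also lower in starvation, as were 60.9% of all bins.

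The 10 named bins with higher density in starvation were 3.63 to 4.24 times higher, and here too the starvation library stood further from its median bin. They held 3.03 to 4.49 times the tags of the median starvation bin, but 0.61 to 0.96 of the median high phosphate bin. The first by the ranking rule lay on chromosome 8 from 190001 to 191000, with 332 starvation tags, 207 high phosphate tags and a log2 ratio of 2.06 (95% exact interval 1.80 to 2.31). Chromosome 16 from 75001 to 76000 had 224 and 137 tags and a log2 ratio of 2.08 (1.77 to 2.40). Chromosome 4 from 1410001 to 1411000 had 273 and 174 tags and a log2 ratio of 2.03 (1.75 to 2.31). The others began at 129001 on chromosome 1, 1477001 on chromosome 4, 222001 on chromosome 5, 1000001 on chromosome 7, 572001 and 703001 on chromosome 10, and 518001 on chromosome 11. Among their 20 adjoining bins, 18 were also higher in starvation, as were 39.1% of all bins.

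**Figure D4:**
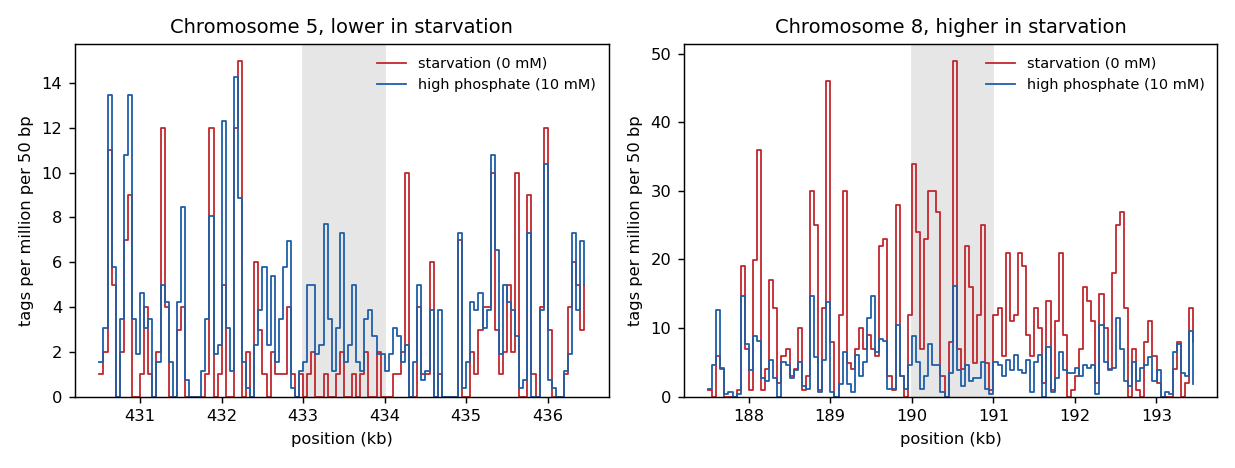
Tags in 50 bp steps, scaled to the nuclear tag total of each library, along chromosome 5 (left) and chromosome 8 (right), positions in kb of the files' build, for the first-ranked lower and the first-ranked higher bin; the grey band marks the named 1 kb bin. In the band starvation holds 13 tags against 166 on chromosome 5, and 332 against 207, from a library with fewer tags, on chromosome 8.

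On a larger scale, chromosomes 3 and 12 held most of the extreme windows. Among 603 windows of 20 kb with at least 500 tags, the highest was chromosome 12 from 460001 to 480000, with a log2 ratio of 0.996 (95% exact interval 0.861 to 1.13). It held only 798 and 1038 tags. Chromosome 3 had 3 of the 5 highest windows, from 40001 to 60000 (log2 ratio 0.67), from 60001 to 80000 (0.70) and from 220001 to 240000 (0.64). The other was chromosome 10 from 460001 to 480000 (0.68). It held 1832 and 2960 tags, against 1565 and 4772 in the window before it and 1187 and 4208 in the window after it. How many positions in these windows can be placed uniquely was not measured. Chromosome 12 had 3 of the 5 lowest windows, starting at 680001, 960001 and 1040001, with log2 ratios of −0.58, −0.58 and −0.70. The other lowest windows were chromosome 16 from 760001 (−0.60) and chromosome 10 from 680001 (−0.57).

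**Figure D5:**
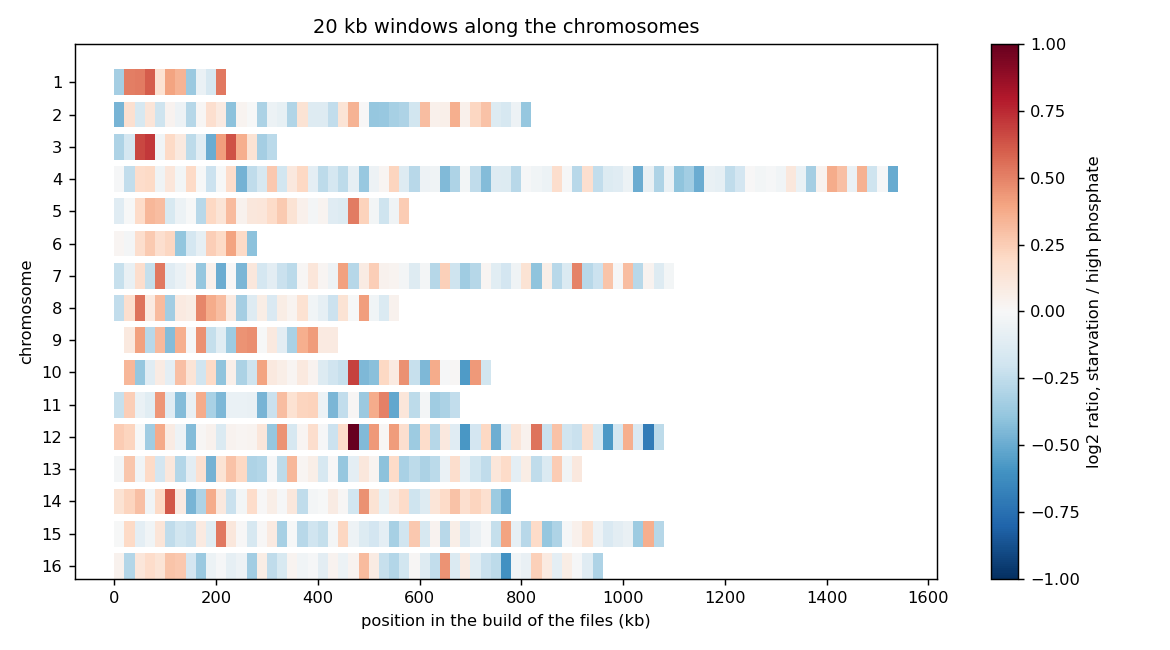
Log2 ratio of scaled tags, starvation over high phosphate (colour), in 20 kb windows along the 16 nuclear chromosomes, position in kb of the files' build. Chromosome 3 shows 3 of the 5 highest windows, between 0.64 and 0.70.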

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

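The tests of explanations here were planned before their results were seen, after the share itself was known. The mitochondrial genome lies outside the nucleosome measurement, and its tags entered none of the ratios of nuclear bins and windows, though they are part of the total behind the chromosome shares. It took 1.16% of the starvation library, above the 0.196% of the high phosphate library. The excess covered every part of the mitochondrial genome that could be compared: 85 of 85 bins of 1 kb with at least 20 tags were at least 2-fold higher in starvation. The median bin had a log2 ratio of 2.93, where a few positions taking most tags would have left it under 1. After the correction for filled positions the log2 ratio of mitochondrial to nuclear tags was 2.73, against 2.58 before, so collapsing of repeat tags argues in the other direction. A larger amount of mitochondrial DNA per cell, a different yield of mitochondrial DNA in the preparation and a base-composition bias stay open. None of them was tested, and each coincides with the single library per condition.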

How the results depend on the processing

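No paired analysis was possible because each condition had 1 library. For the same reason no replicate could be left out. Collapsing to 1 tag per position and strand moved nothing, since the files were already collapsed. Thinning left the fragment length, the repeat, the peak heights and the bin SD within their spread and the counts of 2-fold bins within 1.5 times. Unmoved tags did the same for the bin SD and these counts. With 200 bp bins the SD of the log2 ratio was 1.02 and with 5 kb bins 0.44, against 0.68. The correction for filled positions, added after the data were seen, raised that SD to 0.74. It raised the fragment peak to 3.28 in starvation and 1.499 in high phosphate, and the first array peak to 1.70 and 1.30. Fragment length and repeat stayed within their spread under it. Matching dyads within 40 bp gave 70.2% within starvation, 66.9% within high phosphate, 70.7% for starvation dyads in high phosphate and 57.4% for high phosphate dyads in starvation. Smoothing with an SD of 30 bp gave 59.8%, 48.2%, 54.3% and 41.3%. At 40 bp the starvation dyads thus matched high phosphate as often as they matched each other, with a higher chance level of 36.5% against 29.7%. Scaling the chromosome ratios to nuclear tags, added after the data were seen, raised each by 0.014 and ended the lower value of chromosome 12. All 20 named bins kept their direction under 5 alternatives, which is a weak check for ratios so far from 0. The one that moved most relative to its counting interval lay on chromosome 1 from 129001. It reached a log2 ratio of 2.12 after the correction, at the upper edge of that interval, and was the 1 bin of 20 counted as moved. Alternatives planned for promoters, gene lists, gene starts and CACGTG sites were not run, because no annotation of the files' build was used. At 500000 tags, 57.2% of starvation dyads and 47.2% of high phosphate dyads matched within 20 bp between subsets of their library. Displaced maps matched at 15.2% and 18.5%. Maps at other depths were not made.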

Other observations

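Tests of the 10 kb surroundings, of the even background and of the mitochondrial fragment offset, together with the descriptive trends in this part, were chosen after the data had been seen. DNA near chromosome ends was lower in starvation, and DNA at intermediate distances was higher. Within 5 kb of the outermost tags the log2 ratio was −0.23 (95% exact interval −0.28 to −0.18) and was below 0 on 15 of 16 chromosomes. The mean over chromosomes was −0.29 with an SD of 0.29, a spread that the interval does not cover. At 50 to 100 kb it was 0.124 (0.116 to 0.133) and above 0 on 12 of 16. At 100 to 200 kb it was 0.028 and above 0 on 9 of 16. Beyond 200 kb it was −0.050 and below 0 on 10 of the 13 chromosomes that reach so far. That class leaves out the shortest chromosomes, which were higher in starvation, and no chromosome-wide ratio was taken off. With scaling to the median 10 kb bin the value beyond 200 kb turned to 0.012, while the value within 5 kb was −0.17. Runs of neighbouring 1 kb bins at least 2-fold higher in starvation reached 7 kb, on chromosome 3 from 47001 to 54000 (log2 ratio 1.27), where 100 shuffles of the bins reached at most 5 kb. Another 3 runs spanned 6 kb, on chromosomes 1, 3 and 10. A further 2 runs, on chromosomes 3 and 8, spanned 5 kb, as far as the shuffles reached. Runs of lower bins reached 4 kb, within the 5 kb of the shuffles.

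The log2 ratio of a chromosome's share was lower on longer chromosomes. Across the 16 nuclear chromosomes, which are not independent replicates, Pearson's r was −0.87 and Spearman's rho −0.89. Without chromosomes 4 and 1, the farthest from the median length, r was −0.84. These coefficients describe the same 2 libraries, and no p-value is given.

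The 1 kb bins differed between the libraries with an SD of 0.66 in excess of counting error. The correction for filled positions did not lower this excess, which was 0.71 after it. That argues against collapsing of repeat tags only as far as the correction can undo it. The correction assumes even filling within each 10 bp window. A difference in copy number over 10 kb or more is also argued against as the whole cause, since taking off the surrounding 10 kb left 0.658. Part of the spread may still be regional, since the excess in 10 kb bins was 0.33. In the 11091 of 11560 bins where every 100 bp held a tag the excess was 0.658, so the bins left out did not carry it. That filter removed few bins. It does not measure how many positions in the remaining bins can be placed uniquely, so it decides nothing about those. Base composition was not examined because no sequence of the build was used. It stays open, as do a difference in the digestion or preparation of the single libraries and the phosphate condition itself. None of them was tested for the bins.

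Fragments were 13 bp longer and the peaks of the pair distances higher in starvation. Collapsing is argued against as the whole cause of the heights, since the corrected fragment peaks were 1.499 in high phosphate and 3.28 in starvation. This too assumes even filling within each 10 bp window. Thinning the high phosphate library left its peak at 1.37, which decides nothing about depth, since a ratio of pair counts does not change under random thinning. An even background in the high phosphate library alone would lower both peaks by the same factor. The quotient of the factors was 0.496 (SD over chromosomes 0.063), so background may be at most part of the difference. A candidate explanation for the fragment length alone is trimming or size selection of all DNA in the preparation. On the mitochondrial genome, which carries no nucleosomes, the offset was also longer in starvation, 134 against 125 bp. The difference was 9 bp with an SD of 4.004 bp over 1000 resamplings of 18 blocks. That met the prediction set for this candidate, which keeps it open without singling it out. The mitochondrial peak heights had the opposite order to the nuclear ones, 2.83 in starvation and 4.08 in high phosphate.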
